A study of Mus musculus with 5 samples.

How the data were processed

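Single-cell gene expression was measured in 5 pooled libraries from Renca tumours, 1 per group, each made from 3 mice. The values are deposited UMI counts per gene and barcode, with no normalization by the authors. Per the file headers the PBS counts were made with Cell Ranger 4 and those of the treated libraries with Cell Ranger 7.1.0; the submitters' processing notes name Cell Ranger and the genome build mm9. The annotation is not given in the sources used here. All files list the same 32285 genes. The files of PBS and CD40+CTLA4 list all detected barcodes, including 141680 and 245943 with 0 UMIs. The other 3 list barcodes of 500 or more UMIs only, so a cell call had been applied to them by the authors. One filter was therefore used for all 5.

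Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as implemented in Scanpy 1.11.5, with an expected rate of 0.08. It called 29 cells in PBS, 25 in Triplet and 0 in the other 3 libraries; at 0 of 9999, 16884 and 16389 barcodes it has not worked there. Clusters were made from 2000 variable genes ranked per library, 30 components and 15 neighbours with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, without integration of the libraries, and T and NK cells and mononuclear phagocytes were clustered again. Clusters were named from marker lists, and names ending in -like stand for such clusters. Clusters of under 20 cells, or with fewer than 3 markers at 20 CPM, were left unnamed. So were those with a score under 0.25 at a median under 2500 UMIs, or with another lineage at over 50% of the leading score. The lineage was also left unnamed where another had at least 2 more of the 10 leading genes. For lineages not split into classes a lead of 1 gene was enough. Within T cells and phagocytes the class was left unnamed where another class had more of the 10 leading genes, if only by 1. These thresholds were set after the data had been seen.

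UMIs were summed over the cells of a class and scaled to the UMI total of the class as CPM. Log2 folds use a pseudocount of 5 CPM. Classes with fewer than 50 cells in a library were not compared. Levels have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios of 2 levels exact conditional intervals, all at 95%. Ratios of 2 shares have log-normal 95% intervals made from the cell counts. A count of 0 is given with the share that 3 counts would make. For each of 24 gene lists the median log2 fold over members with at least 20 UMIs was ranked among 10000 random lists matched in 40 bins of expression. A few listed symbols are absent from the files, among them Mx1 and Cxcl11.

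Named genes were, for each comparison and class, the 4 highest and 4 lowest log2 folds among genes with at least 50 CPM and 30 UMIs in the higher library and an interval of the ratio that excludes 2-fold. Mitochondrial, ribosomal, T cell receptor, immunoglobulin, haemoglobin, unnamed predicted, Xist, Tsix and Y-linked genes were left out. Genes more than 5 times higher in a class of another sorted fraction were left out too. Up to 4 members per list and all antibody target genes were added. A gene that met these rules in some comparisons is not reported here, though the counts include it. For each antibody, genes were counted whose lowest level on one side was at least 2 times the highest on the other, and the 4 widest gaps per direction were named where all libraries of the higher side had at least 50 CPM. The 5 comparisons, the 2 comparisons of Triplet with PD1+CD40 and CD40+CTLA4 for lists only, the lists, the cell filter, the rule for named genes and most alternatives were fixed before the data were examined. The 2 comparisons of PD1+CD40 and CD40+CTLA4 with PD1+CTLA4, the removal of top doublet scores, the pooling of all mononuclear phagocytes, the subtraction of T cell folds, the overlap of libraries over clusters and the levels of single genes over whole lineages were chosen after seeing the data.

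The alternatives were a filter of 1000 UMIs and 500 genes, a mitochondrial limit of 20%, doublets kept, Leiden resolution 2, equal cell numbers per library, TMM scaling, pseudocounts of 1 and 20, no low-count filter, cells thinned to 500 UMIs, a gap of any size and of 3-fold, and leaving out each library in turn. Top doublet scores were removed at 0.8% of cells per 1000 cells.

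The folds were tested on simulated data made from monocyte/macrophage-like cells of Triplet and PD1+CTLA4. Counts were Poisson draws around 1 shared profile, with no further spread between cells or libraries. They follow the model behind the intervals, so they do not show how the intervals do where UMIs lie in few cells. The sign was right in 100% of changed genes and the true ratio lay in its interval in 94.3% to 95.2% of draws. Lists of 20 unchanged genes lay at percentiles 0.23 to 96.9, and lists with 12 of 20 genes doubled all at 100. Of 60 genes raised 4-fold in the 3 anti-CD40 libraries, against a rule of 2-fold, 60 were found and 0 unchanged genes were called. No p-value or count of changed genes was made from cells, since cells of 1 library are not replicates. The intervals of shares and of their ratios take cells as independent draws and cover counting error only. Barcodes of clusters without a lineage were left out of all comparisons; T cells and phagocytes without a class name count only in levels and shares over their whole lineage or fraction. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9 were used.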

Results

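Renca cells, a mouse renal cortical adenocarcinoma line, were grown under the skin of Balb/c mice. From day 10 the mice were given 2 doses of PBS or of antibodies into the peritoneum. The antibodies, 200 µg each, were anti-PD-1 and anti-CTLA-4, which block inhibitory receptors of T cells, and agonistic anti-CD40, which activates a receptor of myeloid cells and B cells. The 5 groups were PBS, anti-PD-1 with anti-CTLA-4 (PD1+CTLA4), anti-PD-1 with anti-CD40 (PD1+CD40), anti-CD40 with anti-CTLA-4 (CD40+CTLA4) and all 3 antibodies (Triplet). Tumours were taken 24 h after the second dose. Cells were sorted into T cells (CD45+CD3+), other immune cells (CD45+CD3−) and CD45-negative tumour and stromal cells, and these were mixed 2:1:1 in equal parts from 3 mice. Gene expression was read by droplet sequencing in 1 pooled library per group, so there were no replicates and no difference between groups could be tested. The intervals given are 95% intervals that cover counting error only.

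The files held 61792481 UMIs for PBS, 90313850 for PD1+CTLA4, 73974407 for PD1+CD40, 95867828 for CD40+CTLA4 and 68564874 for Triplet. In the same order, 4375, 9999, 16884, 16389 and 4707 barcodes were used as cells, against 10000 cells loaded per group. Their median depth was 8042, 4779, 1422, 1827 and 13085 UMIs. Clusters left without a name, because they had few UMIs and low marker scores or because genes of more than 1 cell type led them, held 7.11%, 20.9%, 67.2%, 65.0% and 9.39% of them; the thresholds for naming a cluster were set after the data had been seen. Among named cells, T cells made up 13.4%, 30.2%, 9.01%, 7.40% and 27.9%, and CD45-negative cells 20.1%, 20.9%, 0.81%, 1.24% and 8.63%. These parts depart from the mixing ratio, so shares are given only within a sorted fraction. The low numbers of CD45-negative cells rest in part on that naming: an unnamed cluster of 2621 barcodes with a median of 1117 UMIs, led by Cryab, Krt8, Krt18 and collagen genes, held 89 barcodes of PBS, 1171 of PD1+CTLA4, 876 of PD1+CD40, 440 of CD40+CTLA4 and 45 of Triplet. PD1+CD40 held 45 named tumour-like cells and is left out of comparisons of that class.

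The PBS library differed from the 4 treated libraries in T cells and phagocytes, and from the 3 with enough cells in tumour-like cells. Of the UMIs on T cell receptor genes in T cells, 77.8% (76.7% to 79.0%, exact Clopper-Pearson interval) lay on V segments in PBS, against 3.90% to 5.44% in the treated libraries. V segments lie at the 5′ end of these transcripts and the constant segments at the 3′ end. The labels give a 5′ kit for all 5 groups. The share of PBS goes with that label and the shares of the treated libraries do not. Of the cell barcodes of PBS, 3.89% were among the barcodes listed for CD40+CTLA4, against 97.3% to 99.7% of those of the other 3 treated libraries. In monocyte/macrophage-like cells the median absolute log2 fold over genes was 0.458 to 0.487 between PBS and a treated library and 0.089 to 0.308 between treated libraries. Cells of 1 class also lay in separate clusters. The overlap of PBS with a treated library, the sum over clusters of the lower share of cells, was 9.61% to 10.7% in monocyte/macrophage-like, 10.9% to 14.3% in Treg-like and 2.93% to 3.99% in tumour-like cells. Between treated libraries it was 28.8% to 84.02%, 61.9% to 86.7% and 70.8% to 87.6%. Comparisons among treated libraries therefore come first here, and folds against PBS carry this difference.

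**Figure D1:**
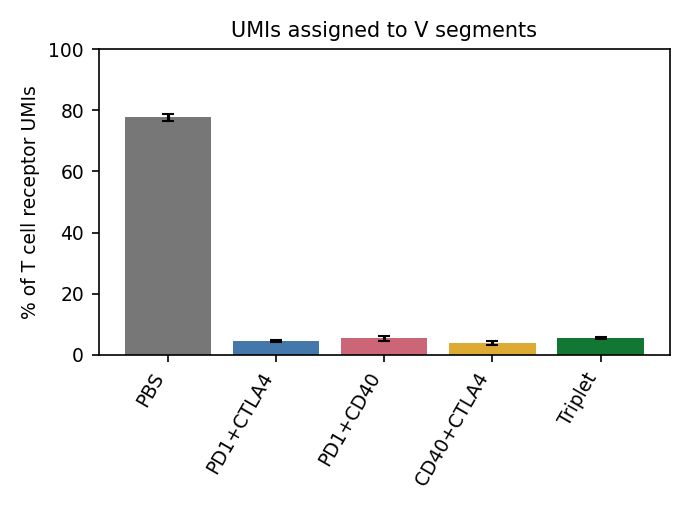
Percent of T cell receptor UMIs in T cells that were assigned to V segments (y axis) in each library (x axis); bars are shares and error bars exact Clopper-Pearson 95% intervals. PBS stands at 77.8% and the treated libraries at 3.90% to 5.44%.

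Triplet against PD1+CTLA4 asks what CD40 agonism adds to blockade of both checkpoints. Monocyte/macrophage-like cells of Triplet had higher levels of Ctsk, the collagen-degrading protease cathepsin K, of the gelatinase Mmp9, and of Mfge8, which bridges dying cells to phagocytes. It had lower levels of interferon-gamma response genes, of genes for MHC class II presentation, and of Plac8, a monocyte gene. Glycolysis and cell cycle genes were higher. Ctsk reached 620.6 CPM (610.2 to 631.2, exact Poisson interval) against 2.371 (1.588 to 3.405), a log2 fold of 6.41 on CPM plus 5. The 13365 Triplet UMIs of Ctsk lay in 292 of 1280 cells. Mmp9 reached 232 against 1.47 CPM (log2 fold 5.20), with 5004 UMIs in 138 cells, Mfge8 reached 181 against 14.96 (3.22), and Plac8 was at 111 against 782 (-2.76). Retnla, a gene of alternative activation, was at 156 against 19.1 CPM (2.74), with its 3356 Triplet UMIs in 61 cells and its 233 PD1+CTLA4 UMIs in 9 cells, 152 of them in 1 cell. Fcgr4, an activating Fc receptor, was at 21.2 against 92.7 CPM (-1.90) and Calhm6 at 26.9 against 112 (-1.87). Jchain also met the rule for named genes at 0.0464 against 69.7 CPM, but all of its 852 UMIs in PD1+CTLA4 lay in 1 cell. None of these 8 genes moved by 2-fold in the same direction in both T cells and tumour-like cells; 2 of them were not measured there.

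Of the 24 gene lists, those of interferon-gamma response, MHC class II presentation and monocyte genes lay below all 10000 random lists of like expression in this class. The interferon-gamma response list had a median log2 fold of -0.85 over 29 measured members (percentile 0), of which 26 were below 0 and 3 above. All percentiles of this kind describe these libraries and are not tests. Among its members, Cxcl9, a chemokine that attracts activated T cells, was at 382 against 1155 CPM. The GTPase genes Gbp4, Gbp2 and Iigp1 were at 41.8 against 160, 47.6 against 157 and 118 against 335 CPM. Cxcl10, also a member, went the other way at 435 against 285 CPM. The list of MHC class II presentation stood at -0.88 (percentile 0), with H2-Aa at 2431 against 4918 CPM, Cd74 at 5022 against 9987 and the class II transactivator Ciita at 77.9 against 201. MHC class I presentation stood at -0.40 (percentile 0.01) and the type I interferon response at 0.02 (82.9). Monocyte genes stood at -0.72 (percentile 0), with Ly6c2 at 25.7 against 179 CPM. Inflammatory macrophage genes were at -0.32 (0.07), and CD40 and NF-kB target genes, which CD40 signalling is known to induce in antigen-presenting cells, at -0.25 (1.05).

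In the same cells, hypoxia and glycolysis genes were at 0.63 (percentile 100), with Bnip3 at 88.7 against 28.8 CPM, Mif at 820 against 387 and Ldha at 692 against 361. Cell cycle genes were at 0.49 (100), with Tyms at 62.4 against 30.7 and Cdk1 at 85.1 against 46.0 CPM. The mix of clusters in the class differed as well. A cluster led by Ube2c and Birc5 held 195 cells of Triplet and 31 of PD1+CTLA4. One led by Mmp12 and Arg1, with Hk2 and Bnip3 among its leading genes, held 127 and 31. Whether the medians in this paragraph come from this mix was not tested. Chemokines were at 0.23 (99.8), where Ccl2, which recruits monocytes, was at 592 against 220 CPM while Ccl17 was at 39.98 against 106. Complement and lipid-associated macrophage genes had a median of 0.15 (92.7), but Spp1 was at 2144 against 539 CPM, Fabp5 at 708 against 183 and Gpnmb at 18.0 against 3.03. Alternatively activated and resident macrophage genes were at 0.08 (88.9) with members apart: Arg1 stood at 38.7 against 6.79 CPM and Chil3 at 2.00 against 25.8. The unfolded protein and stress response was at 0.28 (99.96), led by Hspa1b at 42.6 against 8.34 CPM, and the dissociation immediate early genes at -0.22 (3.4). The epithelial-mesenchymal and matrix list was at 0.09 (86.3). Myeloid checkpoint ligands and receptors were at -0.03 (58.1), dendritic cell maturation at -0.18 (1.56), neutrophil activation at -0.15 (5.83) and antibody target genes at -0.27 (2.81). The 5 lists of T cell genes lay between -0.14 and 0.03 in these cells: cytotoxicity -0.14 (2.80), exhaustion -0.09 (23.8), naive and memory -0.11 (9.87), regulatory T cell 0.03 (67.3) and T helper -0.14 (1.58).

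**Figure D2:**
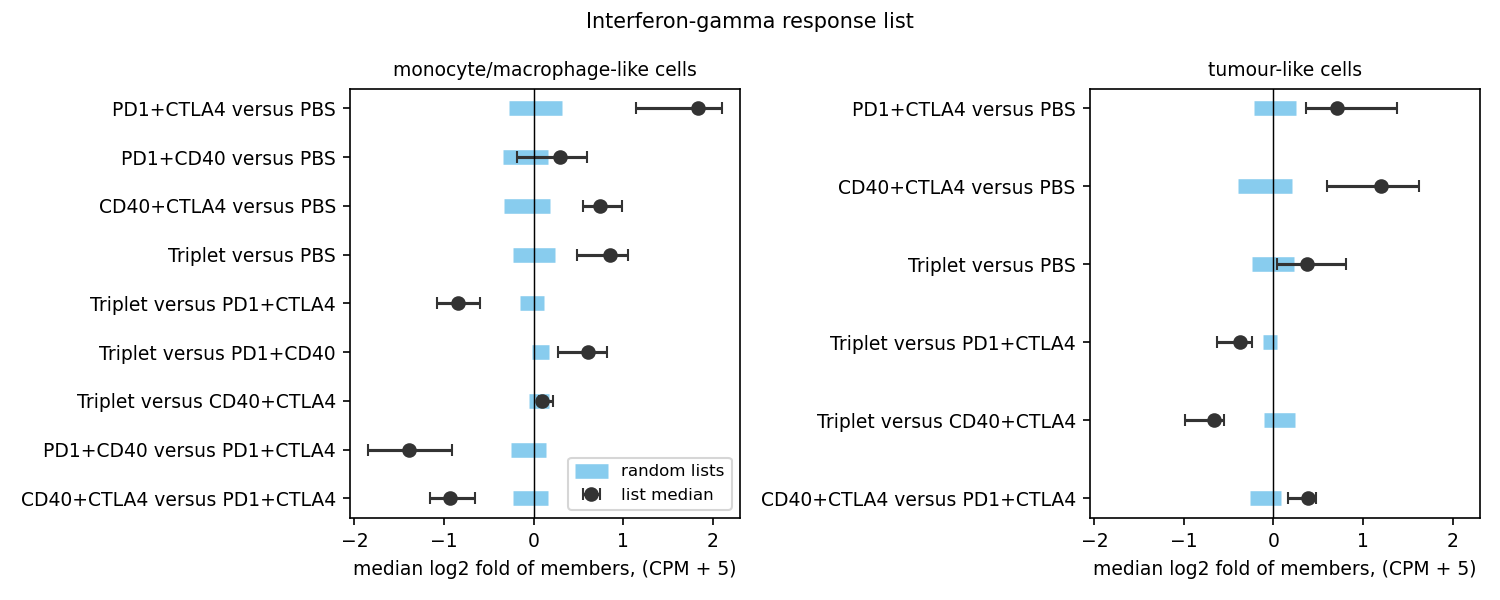
Median log2 fold of the interferon-gamma response list (x axis) in each comparison (y axis) for monocyte/macrophage-like and tumour-like cells. Points are list medians, whiskers their 95% order-statistic intervals over members, and blue bars the 95% range of 10000 random lists matched on expression; PD1+CD40 is absent for tumour-like cells, of which it held 45.

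The phagocytes also differed in kind. Of non-T immune cells (sorted as CD45+CD3−), monocyte/macrophage-like cells made up 47.3% (45.4% to 49.2%) in Triplet and 34.2% (32.7% to 35.7%) in PD1+CTLA4, a ratio of 1.38 (1.30 to 1.47). NK-like cells made up 0.628% (0.366% to 1.00%) and 21.1% (19.8% to 22.4%), plasmacytoid dendritic-like cells 0.369% and 5.17%, and B-like cells 0.148% and 3.44%. With these classes scarcer in Triplet, the higher share of monocyte/macrophage-like cells does not show that they were more numerous. Of mononuclear phagocytes, the class held 1280 of 2592 cells in Triplet and 1323 of 2465 in PD1+CTLA4. The PD1+CTLA4 cells of the monocyte/macrophage-like class lay mostly in a cluster led by Cxcl9 and Gbp2b (384 cells) and clusters led by Retnla and Ccl8 (278), Plac8 and Ifitm6 (214), and Cxcl10 and Rsad2 (140). Triplet shared the Retnla cluster (271 cells) but held 115 cells in the Cxcl9 cluster and 21 in the Plac8 cluster. Most cells of the Retnla cluster held no Retnla UMI, since 61 Triplet and 9 PD1+CTLA4 cells of the whole class held any. A cluster of this class led by Mmp9 and Ctsk held 42 Triplet cells and 0 of PD1+CTLA4. A further cluster led by Acp5, Ctsk and Mmp9, which are osteoclast genes, was left without a class name. It held 7.79% (6.79% to 8.89%) of Triplet mononuclear phagocytes and 0.243% (0.089% to 0.529%) of those of PD1+CTLA4. A cluster of 1240 cells at a median of 15400 UMIs, with macrophage as leading class, was left unnamed because T cell markers were mixed in. It held 575 cells of PD1+CTLA4 and 311 of Triplet, with Ccl8, Mrc1, Cxcl9 and Retnla among its leading genes. These cells are in none of the comparisons.

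Among T cells (sorted as CD45+CD3+), Treg-like cells made up 51.1% (48.3% to 54.0%) in Triplet and 37.4% (35.5% to 39.4%) in PD1+CTLA4, a ratio of 1.37 (1.27 to 1.48). CD8 T-like cells made up 6.73% (5.37% to 8.30%) and 15.6% (14.2% to 17.1%), a ratio of 0.431 (0.342 to 0.544), which went to 0.298 with equal cell numbers per library. Levels over all T cells do not depend on the naming of classes among T cells: Foxp3, the master factor of regulatory T cells, was at 125 CPM (114 to 136) against 74.3 (68.6 to 80.4) and Cd8a at 72.3 (64.4 to 80.7) against 138 (130 to 146). Ifng, the gene for interferon-gamma, was at 94.3 CPM (85.4 to 104) against 237 (227 to 248) over all T cells; it was looked at after the list medians had been seen. In Treg-like cells the exhaustion and inhibitory receptor list was higher in Triplet (median 0.30, percentile 100), with Lag3 at 35.4 against 7.87 CPM and Rgs16 at 45.2 against 15.4. Chemokines were at 0.57 (100), with Ccl4 at 110 against 38.6 CPM; Ccl6 and Lyz2, which are myeloid genes, moved with them at 16.3 against 4.12 and 235 against 112 CPM. Gzma was lower in Treg-like cells at 13.5 against 114 CPM, beside the lower share of NK-like cells, in which it was at 11610 and 10840 CPM.

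CD8 T-like cells reached the minimum of 50 in these 2 libraries only, with 80 Triplet and 372 PD1+CTLA4 cells. Naive and memory T cell genes were higher in Triplet (median 0.50, percentile 100): the homing receptor Ccr7 was at 86.4 against 34.8 CPM and the survival receptor Il7r at 130 against 66.8. Lists of myeloid genes moved with them, with monocyte genes at 0.39 (99.7) and dendritic cell maturation at 0.39 (99.8); some of their members are also T cell genes, such as Ly6c2 at 181 against 126 CPM and Ccl5 at 4049 against 2560. The cytotoxicity list as a whole was at -0.04 (47.5) and exhaustion at -0.05 (42.1). Within them the granzyme genes Gzme and Gzmf were at 43.2 against 1.35 and 37.0 against 2.26 CPM and Gzmb at 196 against 94.8, while Ifng was at 492 against 786 and Pdcd1, which encodes PD-1, at 193 against 311. MHC class II genes were at -0.53 (0.12). The rule for named genes gave Spata7 (log2 fold 2.47), Stfa3 (2.14), Vps26c (1.74) and Penk (1.70) as higher and Xlr (-2.62) as lower. A single Triplet cell held 47 of the 68 UMIs of Spata7, 30 of the 49 of Stfa3 and 39 of the 48 of Vps26c.

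In tumour-like cells, 4 genes met the rule as higher in Triplet than in PD1+CTLA4 and none as lower. Among them were Snhg9 at 61.2 against 20.3 CPM (log2 fold 1.39), Ccl2 at 429 against 173 (1.29) and Traf5 at 51.3 against 20.8 (1.13). Cxcl2 and Cxcl3, which attract neutrophils, were at 59.6 against 15.2 and 31.4 against 6.24 CPM. The interferon-gamma response list was at -0.38 (percentile 0) and MHC class II presentation at -0.78 (0), with Cd74 at 301 against 551 CPM. Transcripts of other cell types moved the same way in these cells, with Apoe at 14.5 against 72.9, C1qa at 17.7 against 54.0 and Ccl5 at 3.41 against 35.5 CPM. Cell cycle genes were at 0.36 (100), with Cdk1 at 111 against 70.8 CPM, and hypoxia and glycolysis genes at -0.19 (0.02).

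Because PBS stood apart, PD1+CD40 and CD40+CTLA4 were also set against PD1+CTLA4; these 2 comparisons were chosen after the data had been seen. The higher Ctsk and Mmp9 and the lower interferon-gamma response genes of Triplet were present in both, but the higher Retnla was not, at 0.0886 CPM (0.0183 to 0.259) in PD1+CD40 and 1.32 in CD40+CTLA4 against 19.1, a level that rests on 9 cells. Of the 8 named genes, 3 in PD1+CD40 and 2 in CD40+CTLA4 moved by at least 2-fold in the same direction in the other lineages measured. Ctsk and Mmp9 were among them in both, with log2 folds in T cells of 2.91 and 1.17 in PD1+CD40 and 3.22 and 1.29 in CD40+CTLA4, and so was Cxcl9 in PD1+CD40. Ctsk in monocyte/macrophage-like cells was at 520 CPM in PD1+CD40 and 759 in CD40+CTLA4 against 2.37 (log2 folds 6.15 and 6.70), and Mmp9 at 179 and 241 against 1.47. Acp5, the acid phosphatase of osteoclasts, was at 108 and 154 against 18.5 CPM. Arg1 was at 37.1 and 70.4 against 6.79. Mfge8 was at 117 CPM in PD1+CD40 against 14.96. Ear2 was lower at 4.90 and 2.72 against 97.7 CPM, and so was the immunoregulatory gene Fgl2 at 21.6 and 34.8 against 243. Cxcl9 was at 93.6 and 258 against 1155 CPM, while Cxcl10 was at 232 and 412 against 285. Fcrls was at 24.9 in CD40+CTLA4 against 197.

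The interferon-gamma response list stood at -1.39 in PD1+CD40 and -0.94 in CD40+CTLA4 against PD1+CTLA4, both at percentile 0. In clusters made without interferon-response genes and counted the same in both libraries, 26.5% and 19.8% of these medians remained. Those clusters held 23.4% of the PD1+CTLA4 cells. An unnamed macrophage cluster led by Cxcl10 was left out, with 611 barcodes of PD1+CD40 and 1506 of CD40+CTLA4 against 3 of PD1+CTLA4. MHC class II presentation stood at -0.62 (0.01) and -0.57 (0.02). Alternatively activated and resident macrophage genes stood at -0.78 and -0.95 (both 0), with F13a1 at 22.6 and 20.5 against 121 CPM. Hypoxia and glycolysis genes were at 0.45 and 0.59 (both 100). Between the 3 libraries given anti-CD40, the interferon-gamma response list was higher in Triplet than in PD1+CD40 by 0.61 (100) and stood at 0.10 (73.8) against CD40+CTLA4. Alternatively activated and resident macrophage genes were higher in Triplet than in both by 0.93 and 1.07 (both 100). Scaling by TMM in place of UMI totals would shift all folds of this class against PD1+CTLA4 by 0.223 for PD1+CD40 and 0.272 for CD40+CTLA4. Neither shift turned the sign of the list medians given here for interferon-gamma response genes.

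Clusters named cDC2-like were far scarcer in PD1+CD40 and CD40+CTLA4 than in the other 3 libraries. Of non-T immune cells, cDC2-like cells made up 0.380% (0.229% to 0.593%) in PD1+CD40 and 0.210% (0.105% to 0.376%) in CD40+CTLA4, against 22.2% (20.9% to 23.6%) in PD1+CTLA4 and 27.0% (25.3% to 28.7%) in Triplet. No cDC1-like cell was found among 4995 in PD1+CD40, which allows up to 0.060%; CD40+CTLA4 held 0.076%, Triplet 0.258% and PD1+CTLA4 1.78%, with a ratio of Triplet to CD40+CTLA4 of 3.38 (0.992 to 11.6). A pair of clusters that scored highest for cDC2 were left unnamed, as genes of other classes were among their leading genes. The one led by Hist1h2ap and Epcam held 362 cells of PD1+CD40, 334 of CD40+CTLA4, 202 of Triplet and 22 of PD1+CTLA4, and the one led by Epcam and Ccl17 held 317, 272, 53 and 19. Mononuclear phagocytes without a class name made up 20.2%, 26.0% and 19.7% of non-T immune cells in PD1+CD40, CD40+CTLA4 and Triplet, against 1.29% in PD1+CTLA4 and 0.259% in PBS. Levels over all mononuclear phagocytes, chosen after these shares were seen, do not depend on the naming of classes among them. The lectin Cd209a was at 0.283 and 0.760 CPM in PD1+CD40 and CD40+CTLA4 against 52.1 in PD1+CTLA4 and 36.2 in Triplet, and Ear2 at 5.89 and 4.12 against 229 and 141. Ear2 is not among the cDC2 markers used for naming, and was also at 97.7 CPM in monocyte/macrophage-like cells of PD1+CTLA4. Of those markers, Mgl2 and Clec10a differed less than Cd209a, with Mgl2 at 254 and 214 against 603 and 436 CPM and Clec10a at 12.8 and 10.8 against 30.6 and 24.8. Ctsk was at 1373 and 2574 CPM in these and 1954 in Triplet, against 46.3 in PD1+CTLA4 and 5.54 in PBS. Acp5 was at 749, 1535 and 989 against 44.7 and 31.9, and the proton pump gene Atp6v0d2 at 80.6, 157 and 121 against 9.33 and 3.02. Of the fusion genes of osteoclasts, Ocstamp followed them at 12.4, 21.4 and 23.1 against 2.64 and 2.06 CPM, while Dcstamp did not, at 21.5, 35.5 and 38.9 against 35.2 and 81.5. Calcr, the calcitonin receptor gene, had 12, 28 and 42 UMIs against 0 and 0. The cluster led by Acp5, Ctsk and Mmp9 held 4.40% (3.81% to 5.05%) of mononuclear phagocytes in PD1+CD40, 9.88% (9.03% to 10.8%) in CD40+CTLA4 and 0 of 2317 in PBS, which allows up to 0.129%. Ctsk in T cells, which should lack it, was at 38.8, 49.4 and 14.9 CPM in the anti-CD40 libraries and 0.823 in PD1+CTLA4.

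**Figure D3:**
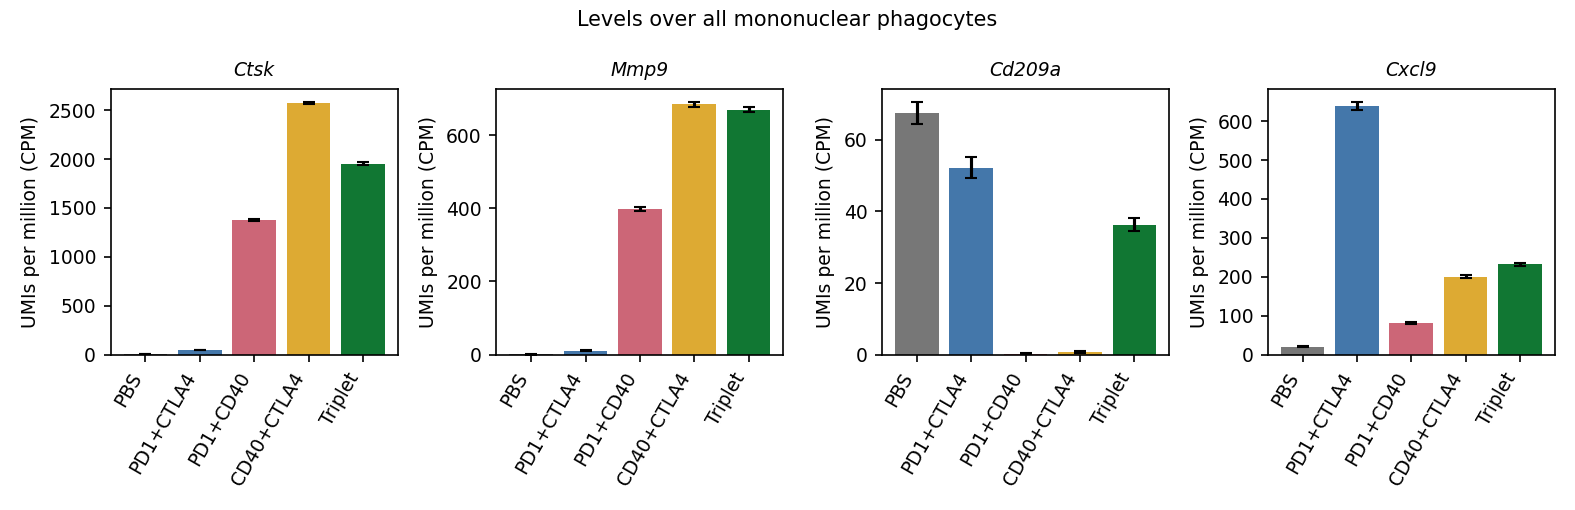
Levels of Ctsk, Mmp9, Cd209a and Cxcl9 over all mononuclear phagocytes in CPM (y axis) in each library (x axis); bars are levels and error bars exact Poisson 95% intervals. Ctsk and Mmp9 are high in the 3 libraries given anti-CD40, Cd209a is below 1 CPM in PD1+CD40 and CD40+CTLA4, and Cxcl9 is highest in PD1+CTLA4.

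Each antibody was given in 3 of the 5 groups, so genes were sought in monocyte/macrophage-like cells whose lowest level with an antibody was at least 2 times the highest level without it, or the reverse. For anti-CD40 there were 23 such genes, 19 higher and 4 lower. By rank alone, 10% of genes would be higher in any 3 libraries than in the other 2, and another 10% lower. Ctsk and Mmp9 had the widest gaps, followed by Fabp5, a fatty acid binding protein, at 735, 970 and 708 CPM with anti-CD40 against 149 (PBS) and 183 (PD1+CTLA4). Mucl1 was lower at 77.7, 42.4 and 80.01 against 265 and 262 CPM. Leaving out a library can only keep or raise such a count. Without the PBS library the count for anti-CD40 was 118, without PD1+CTLA4 561 and without Triplet 90. For anti-CTLA-4 there were 4 genes, all higher, among them Cxcl9, Iigp1 and Gbp2b; the count was 445 without PD1+CD40 and 9 without CD40+CTLA4. For anti-PD-1 the only such gene was Hmox1, which encodes the haem-degrading enzyme, lower at 74.6, 152 and 152 CPM against 686 and 324; the count was 449 without CD40+CTLA4 and 4 without PD1+CD40. In Treg-like cells the counts were 5 for anti-CD40, 6 for anti-CTLA-4 and 5 for anti-PD-1, with Hist1h2ap among those for anti-CD40. Splits of the 5 libraries that match no antibody gave up to 4 such genes in Treg-like cells. In monocyte/macrophage-like cells they gave up to 19, for PD1+CD40 and CD40+CTLA4 against the rest.

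PD1+CTLA4 against PBS asks what blockade of both checkpoints did. In monocyte/macrophage-like cells interferon-gamma response genes and monocyte genes were higher with blockade, and genes of resident macrophages lower, between cells whose overlap over clusters was 10.2%. Cxcl9 was at 1155 CPM (1136 to 1174) against 33.4 (30.3 to 36.7), a log2 fold of 4.92, and Plac8 at 782 against 29.3 (4.52). Gpr141 was at 247 against 9.57 (4.11), while the resident macrophage gene Cbr2 was at 91.4 against 1068 (-3.48). The interferon-gamma response list stood at 1.84 (percentile 100) with Gbp5 at 124 against 10.6 CPM, the type I response at 0.63 (100) with Ifi44 at 167 against 29.4, and monocyte genes at 1.51 (100) with Ly6c2 at 179 against 9.10. Alternatively activated and resident macrophage genes stood at -0.84 (0), with Folr2 at 91.0 against 385 CPM. Cd274, which encodes PD-L1, was at 136 against 40.3 CPM and Pdcd1lg2 at 27.6 against 6.64, while Cd86 was at 135 against 150 and Cd40 at 52.9 against 33.0. In tumour-like cells the interferon-gamma response list stood at 0.71 (100), with Iigp1 at 220 against 20.3 CPM and Gbp2b at 75.6 against 7.22.

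Il31ra, Cfap77 and Coro1b were also lower in these phagocytes, at 8.01 against 356, 4.25 against 179 and 14.96 against 222 CPM. Jchain met the rule as higher, with 852 UMIs in 1 cell against 0 in PBS. Of the 8 named genes, 5 moved by at least 2-fold in the same direction in both other lineages, Cxcl9 among them. In tumour-like cells all 8 named genes did so: Spata7, Iigp1, Chchd2 and Gbp2b were higher, with log2 folds of 3.84, 3.15, 2.77 and 2.72. Il31ra, H2-Q6, Nutf2 and H2-Q1 were lower, with -5.04, -4.57, -4.48 and -4.27. The dissociation immediate early genes moved with the treated side in each class, at -1.35 in monocyte/macrophage-like, -1.40 in Treg-like and -0.90 in tumour-like cells (all percentile 0), with Dusp1 at 91.3 against 601 CPM in the first. Treg-like cells made up 37.4% against 40.5% (36.4% to 44.8%) of T cells, a ratio of 0.923 (0.823 to 1.04), while Foxp3 over all T cells was at 74.3 against 270 CPM. CD8 T-like cells were at a ratio of 2.02 (1.49 to 2.74), which went to 1.08 with finer clusters, and Cd8a over all T cells was at 138 against 223 CPM (203 to 245), the other direction. Levels of single genes against PBS, such as those of Foxp3 and Cd8a, carry the difference of that library. They therefore cannot check these shares. Monocyte/macrophage-like cells were at a ratio of 0.941 (0.881 to 1.01), between 0.744 and 1.11 under other settings. NK-like cells made up 21.1% of non-T immune cells against 3.58% (2.92% to 4.36%), and Ifng over all T cells was at 237 against 85.3 CPM (73.1 to 98.9). Within NK-like cells Ifng went the other way, at 82.7 CPM (70.8 to 96.0) against 168 (126 to 220).

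PD1+CD40 against PBS asks what CD40 agonism did with PD-1 blockade. In monocyte/macrophage-like cells Ctsk was at 520 CPM (512 to 528) against 6.01 (4.74 to 7.52), a log2 fold of 5.58, and Mmp9 at 179 against 0.791 (4.99). S100a4, a calcium-binding protein of monocytes, was at 3603 against 316 (3.49), and Ccdc162 at 126 against 4.43 (3.80). The resident macrophage genes Cbr2 and Fcrls were lower at 60.1 against 1068 (-4.04) and 36.6 against 668 (-4.02). Il31ra (-5.05) and Cfap77 (-3.99) were lower as in the other treated libraries, and 7 of the 8 named genes moved by at least 2-fold the same way in T cells, the other lineage measured here. Monocyte genes stood at 0.97 (percentile 100), the interferon-gamma response at 0.29 (99.9) and alternatively activated and resident macrophage genes at -1.38 (0), with Selenop at 182 against 1986 CPM. Chemokines stood at -0.41 (1.21), with Ccl4 at 16.2 against 331 CPM but Cxcl10 at 232 against 38.1. Dissociation genes stood at -1.63 (0). TMM would shift all folds of this class by 0.192. Treg-like cells made up 59.5% (55.1% to 63.9%) of T cells against 40.5%, a ratio of 1.47 (1.30 to 1.67), while Foxp3 over all T cells was at 133 (117 to 152) against 270 CPM (248 to 293). The Foxp3 levels carry the difference of the PBS library and cannot check the share. CD8 T-like cells were at a ratio of 0.518 (0.309 to 0.870), or 0.295 with finer clusters. Monocyte/macrophage-like cells made up 64.4% (63.1% to 65.7%) of non-T immune cells against 36.3% (34.5% to 38.2%), a ratio of 1.77. With all mononuclear phagocytes pooled it was 1.03.

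CD40+CTLA4 against PBS asks the same with CTLA-4 blockade. Ctsk in monocyte/macrophage-like cells was at 759 CPM (750 to 768) against 6.01 (log2 fold 6.12), Mmp9 at 241 against 0.791 (5.41), S100a4 at 3523 against 316 (3.46) and the interferon-induced chemokine gene Cxcl10 at 412 against 38.1 (3.27). Fcrls (-4.50), Cbr2 (-4.31) and F13a1 (-4.08), all genes of resident macrophages, were lower, as was Il31ra (-5.04); 3 of the 8 were shared by other lineages. The interferon-gamma response list stood at 0.74 (percentile 100), or 0.52 with a pseudocount of 20, and the type I response at 0.60 (100). Monocyte genes stood at 1.51 (100), alternatively activated and resident macrophage genes at -1.65 (0) and dissociation genes at -1.73 (0). TMM would shift all folds of this class by 0.212. The 71 tumour-like cells had an interferon-gamma response list at 1.20 (100), with Cxcl10 at 278 against 2.72 CPM, and CD40 and NF-kB target genes at 1.07 (100). Monocyte genes were at 1.35 (100) in the same cells. Named genes there were Spata7 (5.03), Ubd (4.01), the adhesion molecule Vcam1 (3.32) and Gsta1 (3.12) as higher and Def8 (-5.17), Il31ra (-4.97), Cfap77 (-4.82) and Nutf2 (-4.26) as lower, of which 4 of 8 were shared by other lineages. Ccl2 was at 2046 CPM (1987 to 2106) in these cells, against 173 in PD1+CTLA4 and 358 in PBS. Against PD1+CTLA4 they also had higher Il1rl1 (3.39), Ubd (3.36) and Vcam1 (3.27) and lower Ccn5 (-3.23), Selenop (-3.05), Tshr (-2.86) and Gpx3 (-2.81). Of these 8 genes with Ccl2, 2 were shared by other lineages, Ccl2 and Selenop, and Ccn5 was not measured there. Treg-like cells were at a ratio of 1.23 (1.07 to 1.41) of their share in PBS, while Foxp3 over all T cells went the other way at 74.3 (61.9 to 88.6) against 270 CPM. Here too the Foxp3 levels carry the difference of the PBS library and cannot check the share. CD8 T-like cells were at 1.34 (0.896 to 2.01), which turned to 0.734 with finer clusters. Monocyte/macrophage-like cells were at 1.61, or 1.02 with phagocytes pooled.

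Triplet against PBS asks what all 3 antibodies did together. Among monocyte/macrophage-like cells Ctsk was at 621 CPM against 6.01 (log2 fold 5.83), Mmp9 at 232 against 0.791 (5.36), Ccdc162 at 220 against 4.43 (4.58) and Retnla at 156 against 3.32 (4.27). Il31ra (-4.46), Cfap77 (-3.98), Coro1b (-3.66) and the macrophage gene Ms4a4a (-3.52) were lower, and 4 of the 8 were shared by other lineages. The interferon-gamma response list stood at 0.85 (percentile 100), with Cxcl9 at 382 against 33.4 and Cxcl10 at 435 against 38.1 CPM. The type I response stood at 0.67 (100), monocyte genes at 0.63 (99.99) and alternatively activated and resident macrophage genes at -0.72 (0). The dissociation list stood at -1.46 (0). In tumour-like cells the interferon-gamma response list stood at 0.38 (99.98) and hypoxia and glycolysis genes at -0.95 (0), with Slc2a1, a glucose transporter, at 19.7 against 66.3 CPM. The named genes there were Spata7 (4.76), Snhg9 (2.95), Chchd2 (2.72) and Rabgef1 (2.46) as higher and Il31ra (-4.66), H2-Q6 (-4.56), H2-Q1 (-4.34) and Cfap77 (-4.32) as lower, 7 of 8 of them shared by other lineages. For tumour-like cells TMM would shift all folds by -0.145 here and by -0.153 in PD1+CTLA4 against PBS, and for Treg-like cells by 0.133 here. Treg-like cells were at a ratio of 1.26 (1.12 to 1.42) of their share in PBS, while Foxp3 over all T cells went the other way at 125 (114 to 136) against 270 CPM. As above, the Foxp3 levels carry the difference of the PBS library and cannot check the share. CD8 T-like cells were at 0.870 (0.607 to 1.25), or 0.433 with finer clusters and 0.395 with equal cell numbers. Monocyte/macrophage-like cells were at 1.30, or 1.59 with the cells of highest doublet score removed.

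**Figure D4:**
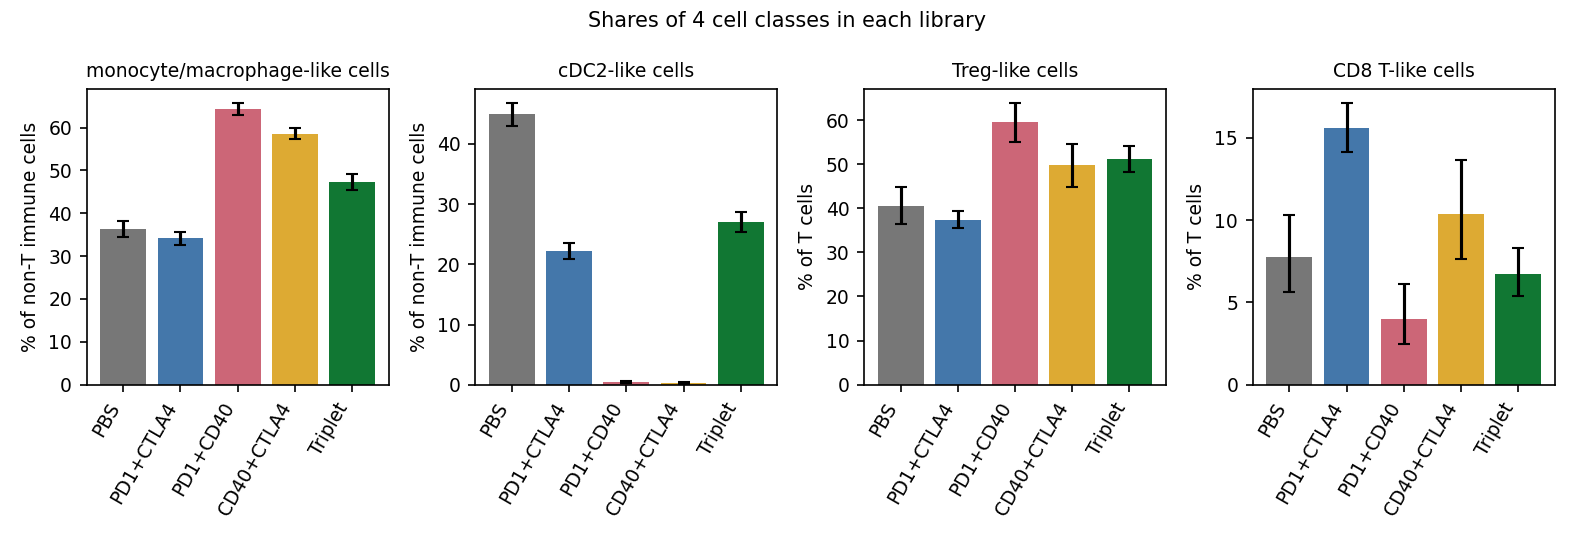
Shares of 4 cell classes (y axes, percent of the cells of their sorted fraction) in each library (x axis); bars are shares and error bars exact Clopper-Pearson 95% intervals. Monocyte/macrophage-like cells range from 34.2% to 64.4% of non-T immune cells and Treg-like cells from 37.4% to 59.5% of T cells.

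The antibody targets were measured where they are known to act. Pdcd1 over all T cells was at 181 CPM in PBS, 127 in PD1+CTLA4, 162 in PD1+CD40, 167 in CD40+CTLA4 and 106 in Triplet. Ctla4 was at 406, 241, 496, 265 and 321, Cd28 at 199, 158, 96.9, 121 and 151, and Cd40lg, the ligand of CD40, at 64.4, 52.7, 18.2, 19.0 and 48.6. In monocyte/macrophage-like cells Cd40 was at 33.0, 52.9, 38.2, 59.2 and 42.9 CPM, Cd274 at 40.3, 136, 56.9, 71.1 and 73.4, Pdcd1lg2 at 6.64, 27.6, 8.18, 12.2 and 9.66, Cd80 at 12.1, 18.6, 18.7, 20.0 and 19.2 and Cd86 at 150, 135, 58.1, 63.2 and 77.7. In mature dendritic-like cells Cd40 was at 349, 175, 404 and 568 CPM in the first 4 libraries. Triplet held 42 such cells and gives no value. An unnamed cluster with mature DC as leading class and Cd40 among its leading genes was left out. It held 948 barcodes of PD1+CD40 and 1295 of CD40+CTLA4, against 41 of PD1+CTLA4 and 9 of PBS.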

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

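Of the tests in this part, that of depth for the interferon-gamma response genes was set before its result was seen and all others were chosen after.

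Barcodes in clusters without a name, which no comparison uses, made up more of each treated library than of PBS, at 20.9% in PD1+CTLA4, 67.2% in PD1+CD40, 65.0% in CD40+CTLA4 and 9.39% in Triplet against 7.11%. The largest such cluster held 15091 barcodes with a median of 1099 UMIs, 8367 of them from PD1+CD40 and 6529 from CD40+CTLA4, and its leading class was macrophage. Free RNA alone is argued against in CD40+CTLA4, the only one of the pair whose file lists barcodes of few UMIs: globin transcripts in that cluster stood at 9.54% of their level in barcodes of 20 to 99 UMIs (948 against 9938 CPM). A part of free RNA is not excluded, since monocyte/macrophage-like cells had 69.5 CPM of globin and the macrophage markers of the cluster (9290 CPM) lay between those of the free RNA (7995) and of these cells (14310). T cells of this library, which the comparisons use, had 1065 CPM of globin (1016 to 1116), so free RNA may be part of their counts too. At least 16389 barcodes passed the filter in each of PD1+CD40 and CD40+CTLA4, more than the 10000 cells loaded, so some of them may not be whole cells; fragments of macrophages, or small cells, stay open and no biological explanation was tested.

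The PBS library stood apart from the treated libraries in the cell classes compared. Depth is argued against: with cells thinned to the same UMIs, in monocyte/macrophage-like and Treg-like cells the lowest median absolute log2 fold of a pair with PBS was 0.498 and 0.634, above the highest of 0.328 and 0.365 between treated libraries; in tumour-like cells this held among pairs without the 71 cells of CD40+CTLA4 (0.469 against 0.261) and among pairs with them (0.783 against 0.635), though not across both. The V segment share of T cell receptor UMIs in PBS exceeded the highest treated share by 72.4 percentage points, and the folds of T cells and phagocytes correlated across genes at 0.718 or more in pairs with PBS against 0.597 or less in others; genes are not independent replicates. That PBS and the treated libraries were read from different ends of the transcripts is therefore a candidate explanation. The labels give a 5′ kit for all groups, which goes with the V segment share of PBS and not with those of the treated libraries. Of PBS cell barcodes, 3.89% were listed for CD40+CTLA4, against 97.3% or more of those of the other treated libraries. This argues against the other Cell Ranger version of PBS as the whole cause, but not as a part of it. An effect of treatment of any kind cannot be told apart from such a difference in reads, since 0 treated libraries were read like PBS.

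Interferon-gamma response genes were lower in monocyte/macrophage-like cells of all 3 libraries given anti-CD40 than in PD1+CTLA4. An unnamed cluster with macrophage as leading class, led by Cxcl10 and with Rsad2 and Cxcl9 among its leading genes, was left out. It held 611 barcodes of PD1+CD40, 1506 of CD40+CTLA4 and 9 of Triplet, against 3 of PD1+CTLA4, at a median of 2301 UMIs. Another unnamed cluster with macrophage as leading class, mixed with T cell markers and with Cxcl9 among its leading genes, was left out too. That cluster held 575 cells of PD1+CTLA4, 165 of PD1+CD40, 138 of CD40+CTLA4 and 311 of Triplet, at a median of 15400 UMIs. How the comparison would stand with the barcodes of either cluster was not tested. A shift common to all cells is argued against, since the list medians after subtraction of the same genes' folds in T cells were -1.25 to -0.653. Depth is argued against as well, since 80.4% to 105% of the medians remained with thinned cells. A different mix of clusters could account for much of it in PD1+CD40 and CD40+CTLA4: with clusters made without interferon-response genes counting the same in both libraries, 29.0% and 21.7% of the median of the same cells remained, and 26.5% and 19.8% of that of the class, over clusters that held 23.4% of the PD1+CTLA4 cells. For Triplet the mix cannot be told apart from a change within clusters, since 64.3% of the median of the same cells remained but 41.5% of that of the class, over clusters that held 40.6% of the PD1+CTLA4 cells; whether anti-CD40 changed the mix or the cells stays open.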

How the results depend on the processing

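No paired analysis was possible because each group is 1 pooled library. The removal of top doublet scores, the pooling of mononuclear phagocytes and the subtraction of T cell folds were chosen after seeing the data. The cause of the moves given here was not tested. All 45 levels of Foxp3, Cd4 and Cd8a over T cells under other settings stayed within their main intervals. So did 111 of 112 medians of the interferon-gamma response list in the 5 comparisons fixed beforehand, in monocyte/macrophage-like and tumour-like cells. None of these medians turned sign, and the other was 0.52 for CD40+CTLA4 against PBS with a pseudocount of 20. In monocyte/macrophage-like cells of Triplet against PD1+CTLA4 this list ranged from -0.97 to -0.62. No value could be had for it in tumour-like cells of PD1+CD40, with 45 cells. Of the other list medians 816 of 915 stayed, 97 moved and 2 turned. These include the interferon-gamma response list of PD1+CD40 and CD40+CTLA4 against PD1+CTLA4. Of the other named genes 400 of 873 stayed, 471 moved and 2 turned. With T cell folds subtracted, chemokines in CD40+CTLA4 against PD1+CTLA4 turned to -0.15 and T cell cytotoxicity genes in PD1+CD40 against PD1+CTLA4 to 0.40. With top doublet scores removed, Jchain turned to 0.0128 in Triplet and 0.00304 in CD40+CTLA4 against PD1+CTLA4.

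Ratios of shares moved in 36 of 95 values. For monocyte/macrophage-like cells, the strict cell filter gave 1.10, 1.61, 1.49 and 1.40 for PD1+CTLA4, PD1+CD40, CD40+CTLA4 and Triplet against PBS and 1.28 for Triplet against PD1+CTLA4. Leiden resolution 2 gave 1.11, 2.03, 1.85 and 1.56 against PBS, and top doublet scores removed gave 1.09, 1.91, 1.87 and 1.59. All mononuclear phagocytes pooled gave 0.744, 1.03, 1.02 and 1.12 against PBS and 1.503 for Triplet against PD1+CTLA4. With doublets kept PD1+CTLA4, CD40+CTLA4 and Triplet were at 1.03, 1.72 and 1.41 against PBS. With equal cell numbers PD1+CTLA4 and Triplet were at 0.797 and 1.52 against PBS and Triplet at 1.91 against PD1+CTLA4, which a mitochondrial limit of 20% put at 1.53. Treg-like cells in PD1+CD40 against PBS were at 1.76 with the strict filter, 1.71 at Leiden resolution 2, 1.80 with equal cell numbers and 1.67 with top doublet scores removed. CD8 T-like cells at Leiden resolution 2 were at 1.08, 0.295, 0.734 and 0.433 for PD1+CTLA4, PD1+CD40, CD40+CTLA4 and Triplet against PBS. With equal cell numbers they were at 1.32 for PD1+CTLA4 and 0.395 for Triplet against PBS and 0.298 for Triplet against PD1+CTLA4.

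The count of genes that separate libraries with and without anti-CD40, anti-CTLA-4 and anti-PD-1 in monocyte/macrophage-like cells was 23, 4 and 1. With a gap of any size it was 6174, 2864 and 4099, with a 3-fold gap 9, 0 and 0, and with all mononuclear phagocytes pooled 37, 2 and 0. A library left out can only keep or raise the count, so the next counts do not show how stable it is. Leaving out 1 library gave 26 to 561, 5 to 445 and 1 to 449: for anti-CD40 118 without PBS, 561 without PD1+CTLA4 and 90 without Triplet; for anti-CTLA-4 445 without PD1+CD40 and 9 without CD40+CTLA4; for anti-PD-1 4 without PD1+CD40 and 449 without CD40+CTLA4. Depth limits the classes with few cells, such as the 80 CD8 T-like cells of Triplet and the 71 tumour-like cells of CD40+CTLA4.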

Other observations

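The test of other splits in this part was chosen after the counts had been seen. Neutrophil-like cells had higher type I interferon response genes in PD1+CD40 and CD40+CTLA4 than in PD1+CTLA4, at medians of 0.85 for PD1+CD40 and 1.32 for CD40+CTLA4 (both percentile 100), while Triplet stood at -0.50 (0.01) and -0.79 (0) against them. Against PBS the list stood at 1.29 in PD1+CTLA4, 1.48 in PD1+CD40, 1.98 in CD40+CTLA4 and 1.06 in Triplet, but these compare different clusters: the overlap of PBS with a treated library over the neutrophil-like clusters was 10.3% to 15.2%, against 95.1% to 99.7% between treated libraries. Neutrophil-like cells made up 3.03% (2.42% to 3.75%) of non-T immune cells in Triplet and 6.15% to 9.23% in the other 4 libraries.

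Mature dendritic-like cells, in which CD40 is known to be highly expressed, had higher CD40 and NF-kB target genes in PD1+CD40 and CD40+CTLA4 than in PD1+CTLA4, at 0.38 (percentile 99.97) and 0.31 (99.7), and higher chemokines at 0.91 and 1.06 (both 100). Monocyte genes were higher in PD1+CD40 as well, at 0.52 (99.87). These medians rest on 147 named cells of PD1+CD40, 139 of CD40+CTLA4 and 162 of PD1+CTLA4. An unnamed cluster with mature DC as leading class was left out, with 948, 1295 and 41 barcodes of these libraries. In cDC2-like cells of Triplet against PD1+CTLA4 the CD40 and NF-kB target genes were at 0.23 (100), with the adhesion molecule Icam1 at 64.1 against 41.6 CPM, Bcl2a1a at 297 against 197 and the costimulator Cd80 at 41.3 against 27.3. The unfolded protein and stress response was at 0.39 (100) in these cells, with the heat shock genes Hspa1b at 115 against 0.681 and Hspa1a at 68.7 against 2.38 CPM. Conventional CD4 T-like cells of Triplet had higher naive and memory T cell genes than those of PD1+CTLA4, at 0.25 (100).

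For the genes that separate the 3 libraries given anti-CD40 from the other 2 in monocyte/macrophage-like cells, the 10 splits of 5 libraries into 3 and 2 are too few for a share under 0.05. The real split gave 23 genes, the highest of the others gave 19, and 1 split gave as many as the real one, itself.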
